A study of Mus musculus with 6 samples.

How the data were processed

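RNA from liver of WT and Arid2 LKO mice was sequenced in 6 libraries. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit, and 1 μg per sample entered a NEBNext Ultra RNA library preparation for Illumina sequencing. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the genome build mm10, without saying what each was used for. The annotation release, the strand setting and filters are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

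The authors deposited 1 table per library with 54532 gene identifiers and 1 value each, and the values were FPKM. The unit was read from the values. Each FPKM multiplied by the merged exon length of the gene in GENCODE vM21 fell on multiples of 1 step per library, and between 96.1% and 96.4% of values above 0 were whole within 0.05 read. The steps gave 13947787 to 18159285 reads per library. Whether a unit is a read or a fragment is not stated. The totals implied by the steps, 12704131 to 19279637, followed median-of-ratios size factors within a ratio of 0.995 to 1.00 and not the sums of reads, so a scaling between libraries appears to be part of the deposited FPKM; no label says so. Symbols and coordinates come from GENCODE vM21, on mm10, which held 54495 of the identifiers. No 2 libraries shared an identical FPKM above 0 for any gene.

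The design had been written for counts. Because the files held FPKM, the test named there for normalized values was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) with robust empirical Bayes, over the 11672 genes with a mean of at least 0.5 FPKM across the 6 libraries, genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale and understate changes of low genes. Standard deviations are over the FPKM of 3 libraries. Of 50 gene lists fixed before the data were examined, the 46 with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Sex chromosome genes and markers of T and NK cells, exocrine pancreas and skeletal muscle had fewer tested members.

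Genes named in the text followed a rule written before the data were examined. It named Arid2, Jak2, Stat5a, Stat5b, Nedd4l, Pparg and Cd36 whatever their values. It further named up to 12 genes per direction with the largest change among those past the threshold, with a mean of at least 1 FPKM, non-overlapping groups and an established symbol, which gave 4 genes. It also named up to 4 members with the smallest p of each list described, and sex chromosome genes. Gm31583 was named in addition.

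The fit was tested on simulated data for the same comparison, with 11671 genes and 200 of them changed. It called 11.3% of 62 genes changed 2-fold, 54.2% of 59 genes changed 4-fold and 91.1% of 79 genes changed 16-fold, all 111 with the right sign, and 9 unchanged genes. Genes changed 2-fold would therefore mostly be missed with these 6 libraries. Camera called 0 of 20 unchanged sets. The simulated genes varied independently of each other, so this does not test camera on lists whose members vary together.

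Alternatives fixed before the data were examined and run were a pseudocount of 0.1, no filter, a mean of at least 1 FPKM, the replicate number as a block, each library left out in turn, other windows around Arid2, camera with an estimated correlation, and fry. Alternatives added after seeing the data were voom on the recovered reads, scaling to library totals, quantile normalization, leaving out both replicate 1 libraries, array quality weights, protein-coding genes alone, a correction for GC content (lowess span 0.3), and sex-biased lists without multigene families. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.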

Results

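Liver RNA of wild-type (WT) mice and of mice described as lacking Arid2 in the liver (LKO) was sequenced in 6 libraries, 3 per genotype, all from untreated animals. ARID2 is a DNA-binding subunit of the PBAF chromatin remodelling complex. The series title places the comparison in the context of hepatic steatosis and the kinase JAK2, so the question was which liver transcripts differed between the genotypes. The values were FPKM, which are relative to merged exon length and to a library scale that followed median-of-ratios size factors, not sums of reads. Their steps corresponded to 16889737, 17312282 and 16140525 reads in WT replicates 1 to 3 and to 13947787, 16894024 and 18159285 reads in LKO replicates 1 to 3. At this depth, 3 reads on a transcript of 1 kb corresponded to between 0.156 and 0.236 FPKM, a floor that covers counting error only. Between 16190 and 18152 genes were above 0 per library. Labels give the libraries as separate samples but do not say that each came from a separate animal, so p-values measure the spread between these samples.

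The 2 libraries numbered 1 stood apart from the other 4. They had 2003 (WT) and 2368 (LKO) genes with 1 to 5 reads, against 3913 to 4263 in the other 4 libraries. Genes of the mitochondrial genome took 20.7%, 10.2% and 18.5% of reads in WT replicates 1 to 3 and 27.6%, 7.72% and 4.76% in LKO replicates 1 to 3. The first principal component held 43.7% of the variance and placed both replicate 1 libraries at its lower end (-42.6 and -46.9). The second held 29.1% and placed the 3 WT libraries between -31.7 and -21.9 and the LKO libraries at 41.6, 36.3 and 0.31.

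**Figure D1:**
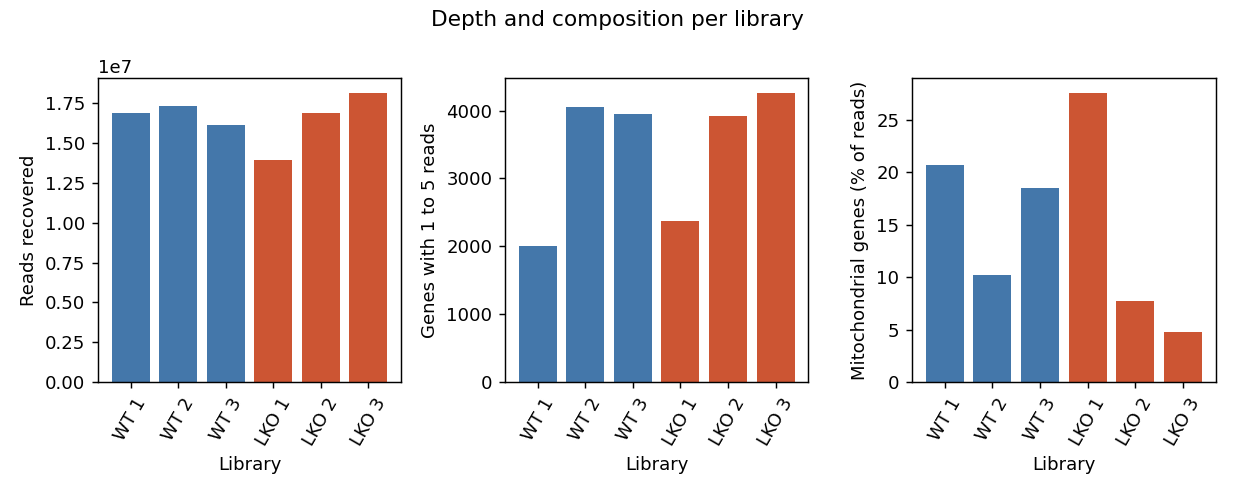
Bars give, for each library on the horizontal axis, the number of reads recovered, the number of genes with 1 to 5 reads and the percentage of reads on mitochondrial genes, with WT in blue and LKO in orange. Both replicate 1 libraries have fewer genes with 1 to 5 reads (2003 and 2368) than the other 4 (at least 3913).

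The targeted gene did not separate the groups. Arid2 (ENSMUSG00000033237, chromosome 15, 96287518 to 96404992, plus strand, mm10) was at 2.65, 1.74 and 1.79 FPKM in WT replicates 1 to 3, from 549, 328 and 300 reads. It was at 2.55, 1.33 and 2.04 FPKM in LKO replicates 1 to 3, from 348, 223 and 417 reads. The log2 difference on the log2(FPKM + 1) scale was -0.05 ± 0.24 (SE; limma, 95% interval -0.62 to 0.52, adjusted p = 0.974), and its sign turned without WT replicate 1 (0.09) or without LKO replicate 2 (0.12). The values are sums over the whole gene, so reads over a deleted exon could not be viewed separately. Arid2 therefore did not check the genotype labels, and every direction below is between libraries labelled WT and libraries labelled LKO. All 6 libraries had the transcripts of male animals: the Y-linked gene Ddx3y lay between 8.16 and 11.97 FPKM, and Xist, transcribed from the inactive X of females, was at most 0.046 FPKM.

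In the libraries labelled LKO, Hsd3b5, Cdhr5 and Susd4 fell to means of 1.16 FPKM or less, and the cytoskeletal gamma-actin gene Actg1 rose. Of 11672 genes tested, 1 rose and 4 fell (limma-trend, adjusted p under 0.05), and all 5 changed at least 2-fold. Hsd3b5, a hydroxysteroid dehydrogenase of male mouse liver (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252, minus strand), fell from 88.3 ± 33.2 to 0.450 ± 0.450 FPKM (mean ± SD, n = 3 per group; log2 difference -5.92 ± 0.36 SE, limma adjusted p = 0.00482). It had 1803, 3405 and 1922 reads in the WT libraries and 19, 6 and 4 in those labelled LKO. Cdhr5, a protocadherin of epithelial brush borders (ENSMUSG00000025497, chromosome 7, 141269083 to 141276786, minus strand), fell from 29.6 ± 2.58 to 1.16 ± 0.752 FPKM (log2 difference -3.87 ± 0.29 SE, limma adjusted p = 0.0114). Susd4, which encodes a regulator of complement (ENSMUSG00000038576, chromosome 1, 182763860 to 182896591, plus strand), fell from 12.5 ± 3.79 to 0.306 ± 0.162 FPKM (log2 difference -3.33 ± 0.28 SE, limma adjusted p = 0.0168). Actg1 (ENSMUSG00000062825, chromosome 11, 120345690 to 120348542, minus strand) rose from 10.4 ± 0.299 to 78.7 ± 13.7 FPKM (log2 difference 2.79 ± 0.26 SE, limma adjusted p = 0.0254). The remaining call was the long non-coding RNA Gm31583 (ENSMUSG00000115919, chromosome 16, 24085083 to 24090089, minus strand), named because the calls were few and after its values were seen. It fell from 11.2 ± 1.99 to 1.44 ± 0.361 FPKM (log2 difference -2.32 ± 0.24 SE, limma adjusted p = 0.0422). Hsd3b5 and Actg1 have close copies with which reads may be shared, so their levels are uncertain to that extent.

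The number of calls changed when 1 library, and so part of the samples, was left out. The log2 differences of the called genes then stayed between -6.16 and -5.64 for Hsd3b5, -4.14 and -3.73 for Cdhr5, -3.59 and -3.19 for Susd4, -2.43 and -2.19 for Gm31583, and 2.66 and 2.91 for Actg1. No gene was called by limma without WT replicate 3, where 652 had an unadjusted p under 0.05, and 13 genes rose and 4 fell without LKO replicate 3. Without WT replicate 1, 1 gene rose and 1 fell, as was the case without both replicate 1 libraries. The counts were 0 and 4 without WT replicate 2, 0 and 3 without LKO replicate 1, and 1 and 2 without LKO replicate 2. With the replicate number as a block, an alternative fixed in advance, 0 genes rose and 0 fell. Array quality weights, added after seeing the data, gave 621 and 574 genes, and no filter gave 0 and 1; with quantile normalization, 0 rose and 3 fell. An unadjusted p under 0.05 was found for 1076 genes, 500 higher and 576 lower, where 584 would be expected by chance. Other splits of these 6 libraries gave between 89 and 2595 such genes, so a count above 584 does not by itself point to genotype. Groups did not overlap for 15.4% of genes (934 above, 866 below), where chance gives 10% for 3 against 3. An exact permutation test of any single gene cannot go under p = 0.1 here. None of the 135 tested genes within 10 Mb of Arid2 was called (Fisher's exact test, two-sided, p = 1), but with 5 calls only 0.0578 would be expected there by chance, so this count says nothing about effects around Arid2.

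**Figure D2:**
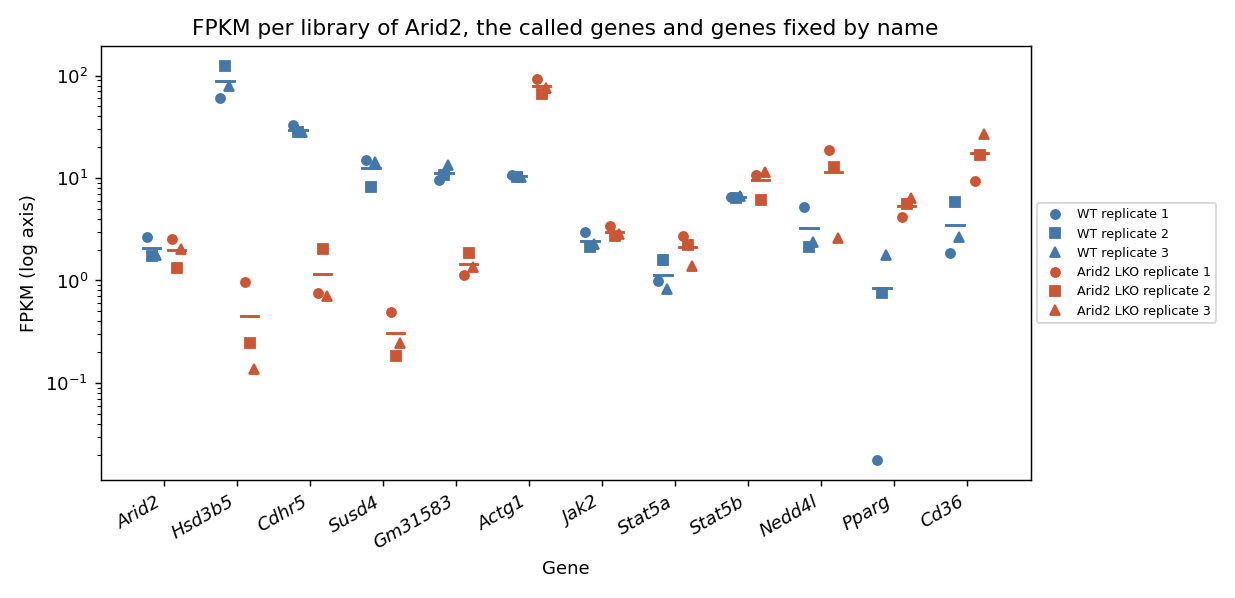
Points give the FPKM of each library on a log axis for Arid2, the 5 called genes and 6 genes fixed by name, with WT in blue and LKO in orange, a marker shape per replicate number and a bar at the mean of 3 libraries. Arid2 overlaps between the groups (1.33 to 2.65 FPKM), while Hsd3b5 lies at 60.4 FPKM or above in WT and at 0.966 or below in LKO.

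Genes of the JAK2 and steatosis context were fixed by name, and none of them passed the threshold (limma). Jak2 was at 2.46 ± 0.479 FPKM in WT and 2.97 ± 0.361 in libraries labelled LKO (SD, n = 3; limma log2 difference 0.21 ± 0.21 SE, adjusted p = 0.842). Its 95% interval of -0.29 to 0.70 covers both directions. Stat5a (1.13 ± 0.391 against 2.11 ± 0.676 FPKM, limma adjusted p = 0.584) and Stat5b (6.53 ± 0.203 against 9.46 ± 2.91 FPKM, limma adjusted p = 0.721), the transcription factors activated by JAK2, overlapped between groups or varied within LKO. Nedd4l, a ubiquitin ligase, was at 18.7 and 12.8 FPKM in LKO replicates 1 and 2 but at 2.58 in LKO replicate 3, against 2.15 to 5.18 in WT. Pparg, a lipogenic nuclear receptor, was above every WT library in every LKO library (0.849 ± 0.884 against 5.37 ± 1.08 FPKM; log2 difference 1.89 ± 0.37 SE, limma adjusted p = 0.187). The same held for the fatty acid transporter Cd36 (3.45 ± 2.08 against 17.6 ± 8.66 FPKM; log2 difference 2.05 ± 0.46 SE, limma adjusted p = 0.231).

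Gene lists fixed in advance were compared with all other genes by camera, with a preset correlation of 0.01, and 13 of 46 lists were called. None of the 13 calls held with an estimated correlation, and none with fry, a rotation test. With an estimated correlation camera also takes its p-value from the residual degrees of freedom, of which 6 libraries leave few. For the lipid droplet list the estimate was 0.034 against the preset 0.01, yet the unadjusted camera p went from 1.61e-04 to 0.0299. A lost call therefore does not by itself show that the members of a list vary together. Preset camera also called 8 to 18 lists in the 9 other splits of these 6 libraries. The lists below are therefore given with both p-values.

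Of 25 male-biased genes tested, 2 fell, Hsd3b5 and Susd4, 0 rose, and 23 did not pass; adjusted over the list alone, 8 fell and 1 rose. Their median log2 difference was -1.14, with 21 of 25 below 0 (camera adjusted p = 1.27e-09; adjusted p = 0.687 with an estimated correlation). The list was lower in every LKO library (-1.24, -1.49 and -1.85 on the log2 scale, against -0.28 to 0.21 in WT). Cyp2u1, a cytochrome P450, was at 10.7 ± 1.89 FPKM in WT and 1.61 ± 0.427 in LKO (limma adjusted p = 0.0583). Selenbp2, a selenium-binding protein, was at 528 ± 423 and 2.49 ± 1.92 FPKM (limma adjusted p = 0.135) and passed without WT replicate 2, at 49.7 FPKM the lowest in WT (limma adjusted p = 0.0142). With another library left out, the limma adjusted p of Selenbp2 reached 0.533. None of the 19 female-biased genes passed over all genes; adjusted over the list alone, 6 rose and 0 fell. Their median was 1.15 (camera adjusted p = 1.92e-06; adjusted p = 0.699 with an estimated correlation). It was 0.70 without LKO replicate 3, 0.41 without a filter on low values and 2.19 with voom, added after seeing the data. The peroxisomal oxidase gene Hao2 was at 0.196 ± 0.0957 FPKM in WT and 5.76 ± 4.13 in LKO (limma adjusted p = 0.153). Cyp2c69 was at 1.32 ± 1.83 and 42.2 ± 44.7 FPKM, and Cyp2c40 at 4.07 ± 5.65 and 37.7 ± 22.7 FPKM. Both WT means rested on WT replicate 3 (3.44 and 10.6 FPKM), without which the log2 differences moved from 3.98 to 4.58 and from 3.38 to 4.28. Both were also highest in LKO replicate 3 (93.7 and 63.8 FPKM). Cyp2c members share long stretches of sequence, and their values are uncertain.

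Of the lists on lipid metabolism, 2 were called by camera with the preset correlation, and others were not. Of 16 lipid droplet and PPAR-gamma target genes none passed over all genes; adjusted over the list alone, 4 rose and 0 fell. Their median was 0.75 (camera adjusted p = 9.26e-04; adjusted p = 0.687 with an estimated correlation), and 0.19 without a filter on low values. Besides Pparg and Cd36, the lipid droplet coat gene Plin2 was at 56.9 ± 45.6 FPKM in WT and 227 ± 71.6 in LKO. Cidec, which acts in droplet fusion, was at 2.14 ± 0.376 and 44.0 ± 34.1 FPKM, with 4.71 in LKO replicate 3, without which it passed (limma adjusted p = 0.0165). With another library left out, the limma adjusted p of Cidec reached 0.894. Of 39 fatty acid oxidation and PPAR-alpha target genes none passed over all genes; adjusted over the list alone, 1 rose. Their median was 0.52, with 36 above 0 (camera adjusted p = 2.90e-06; adjusted p = 0.770 with an estimated correlation). The median was 0.24 without WT replicate 1 and 0.81 without WT replicate 2, and on the list's log2 scale WT replicate 2 (0.69) lay above LKO replicate 1 (0.43). Acot2 was at 2.06 ± 1.10 and 11.5 ± 3.59 FPKM, Pdk4 at 0.403 ± 0.204 and 5.57 ± 5.46 (11.8 in LKO replicate 1), and Cyp4a10 at 71.7 ± 59.9 and 325 ± 39.1. Cyp4a14, also on the female-biased list, was at 1.08, 51.4 and 3.57 FPKM in WT replicates 1 to 3 and at 145 ± 77.3 in LKO; its log2 difference moved from 4.07 to 5.43 without WT replicate 2 (limma adjusted p = 0.0753). De novo fatty acid synthesis (20 genes, median -0.29, camera adjusted p = 0.164), triglyceride synthesis (14 genes, camera adjusted p = 0.707) and fatty acid uptake and binding (18 genes, camera adjusted p = 0.583) were not called. The sign of the de novo synthesis median was not stable (-0.51 to 0.12 over the settings). On that list's log2 scale LKO replicates 1 to 3 lay at -1.06, -0.14 and 0.45.

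Of 28 acute phase genes none passed over all genes; adjusted over the list alone, 1 rose. Their median was 1.02 (camera adjusted p = 9.52e-05; adjusted p = 0.731 with an estimated correlation). LKO replicates 1 and 2 lay at 1.27 and 1.88 on the list's log2 scale, LKO replicate 3 at 0.06, and the WT libraries between -0.36 and 0.19. The median was 0.65 without LKO replicate 2. Lcn2, which binds bacterial siderophores, was at 140 and 376 FPKM in LKO replicates 1 and 2, at 6.66 in LKO replicate 3 and at 0.67 to 7.81 in WT. Itih4, a plasma protease inhibitor family member, was higher in every LKO library (231 ± 15.4 against 664 ± 38.4 FPKM, limma adjusted p = 0.175). The neutrophil list, with 5 genes tested, varied in the same way (camera adjusted p = 0.0123; adjusted p = 0.699 with an estimated correlation), at 1.31, 1.00 and 0.14 in LKO replicates 1 to 3; S100a9 was at 1.22 ± 1.23 FPKM in WT and 4.97 ± 3.04 in LKO. Immediate early genes, a sign of tissue handling as well as of signalling, had a median of 0.86 (16 genes, camera adjusted p = 3.06e-04, and 0.699 with an estimated correlation). Adjusted over the list alone, 2 rose. LKO replicates 1 to 3 lay at 1.49, 0.12 and 1.11 on that list's log2 scale and WT between -0.38 and 0.30, so LKO replicate 2 lay within WT. Btg2 was at 4.25 ± 1.57 FPKM in WT and 47.6 ± 27.9 in LKO. The median of the immediate early list was 0.52 without LKO replicate 1, 0.50 without both replicate 1 libraries and 0.35 with array quality weights. The endoplasmic reticulum and integrated stress list (26 genes, median 0.46, camera adjusted p = 0.00171; adjusted p = 0.699 with an estimated correlation) was led by Asns, asparagine synthetase, at 2.19 ± 3.56 and 20.2 ± 1.98 FPKM. Its WT mean rested on WT replicate 1 (6.30 FPKM, against 0.042 and 0.234 in WT replicates 2 and 3), and without that library the log2 difference moved from 3.32 to 4.22 and Asns passed (limma adjusted p = 0.0171). With another library left out, the limma adjusted p of Asns reached 0.713. The integrated stress list lay at 0.33, 0.91 and 0.58 in LKO replicates 1 to 3 and at -0.30, 0.15 and 0.16 in WT. Its median was 0.19 without WT replicate 1, 0.24 without LKO replicate 2 and 0.70 without LKO replicate 1. All 18 heat shock genes were fitted above 0 (median 0.39, camera adjusted p = 6.28e-04; adjusted p = 0.868 with an estimated correlation), with Hspb1 at 10.2 ± 3.87 and 48.2 ± 12.3 FPKM. Their median was 0.18 without WT replicate 1, 0.22 without LKO replicate 2 and 0.69 without LKO replicate 1, and LKO replicate 1 (0.23) lay below WT replicates 2 (0.25) and 3 (0.26). For the integrated stress and heat shock lists 1 gene rose adjusted over the list alone and none over all genes.

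JAK-STAT pathway components lay slightly higher (27 genes, median 0.34, camera adjusted p = 0.0109; adjusted p = 0.699 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The call ended without LKO replicate 1 (median 0.20, adjusted p = 0.0932). Stat3 was at 7.27 ± 0.154 FPKM in WT and 18.8 ± 5.28 in LKO (limma adjusted p = 0.232), and the interleukin 6 receptor subunit gene Il6st at 6.03 ± 0.285 and 9.96 ± 0.509. The 3' ends of Stat3 and Stat5a overlap on opposite strands, and whether counting used strand is not given in the sources used here. Growth hormone and STAT5 response genes (16 genes, median 0.17, camera adjusted p = 0.583) and the NEDD4-family and JAK2-linked ubiquitin ligases (13 genes, camera adjusted p = 0.804) were not called, nor were the PBAF and BAF subunits (24 genes, camera adjusted p = 0.590). On the growth hormone list's log2 scale LKO replicates 1 to 3 lay at 0.46, 0.36 and -0.44, against -0.11 to 0.06 in WT.

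Interferon response genes lay lower, with 27 of 33 below 0 and a median of -0.26 (camera adjusted p = 6.16e-04; adjusted p = 0.699 with an estimated correlation); none passed over all genes or adjusted over the list alone. The median was -0.40 without LKO replicate 1, -0.43 with a pseudocount of 0.1 and -0.52 with voom. Ifit1 was at 2.45 ± 0.308 FPKM in WT and 0.932 ± 0.374 in LKO, and the interferon-inducible GTPase gene Ifi47 at 2.68 ± 0.455 and 1.03 ± 0.506. Among markers of blood and immune cells, 5 of 6 haemoglobin and erythroid genes lay below 0 (median -0.72, camera adjusted p = 0.0123, and 0.699 with an estimated correlation). Of 6 B and plasma cell genes 4 lay below 0 and 2 above (median -0.79, camera adjusted p = 0.0305, and 0.699 with an estimated correlation). Every LKO library was below every WT library for 3 of these B and plasma cell genes and above for 1. Adjusted over the list alone, 1 erythroid gene and 2 B and plasma cell genes fell. Alas2, an enzyme of haem synthesis in red cell precursors, was at 27.7 ± 15.6 and 3.69 ± 1.96 FPKM, and the immunoglobulin gene Ighm at 8.62 ± 3.73 and 1.43 ± 0.997. Alas2 was the only erythroid gene with every LKO library below every WT library, and Hba-a1, Hba-a2 and Hbb-bt overlapped between the groups. The erythroid call ended without WT replicate 2 (median -0.38, adjusted p = 0.110), and its median was -1.22 without WT replicate 3 and -0.43 with array quality weights. The neutrophil call ended without WT replicate 2 (adjusted p = 0.0747), without LKO replicate 1 (adjusted p = 0.172) and without a filter on low values (median 0.38, adjusted p = 0.0954); its median was 0.62 with all libraries, 2.08 with a pseudocount of 0.1, 2.09 with voom and 1.14 with array quality weights. The B and plasma cell call ended without WT replicate 1 (median -0.41, adjusted p = 0.0869), LKO replicate 3 (adjusted p = 0.202) or both replicate 1 libraries (median -0.49, adjusted p = 0.0531), with library totals (adjusted p = 0.0705) and with quantile normalization (adjusted p = 0.0658); its median was -0.19 without a filter on low values and -1.22 with voom. Markers of hepatocytes (camera adjusted p = 0.404), Kupffer cells and macrophages (camera adjusted p = 0.626), sinusoidal endothelium (camera adjusted p = 0.124), stellate cells (camera adjusted p = 0.473) and cholangiocytes (camera adjusted p = 0.626) were not called.

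**Figure D3:**
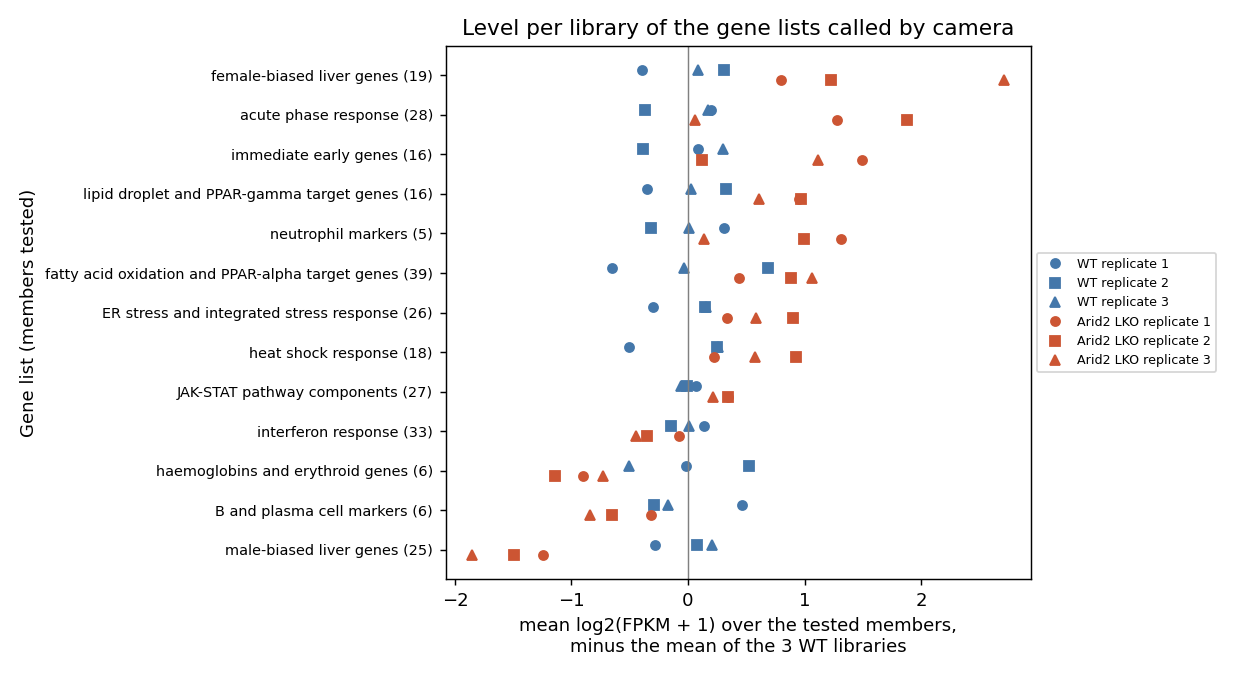
Points give, for each called list (vertical axis, members tested in brackets) and library, the mean log2(FPKM + 1) of the members minus the mean of the 3 WT libraries (horizontal axis), with WT in blue, LKO in orange and a marker shape per replicate number. The male-biased list lies at -1.24 or below in every LKO library and at -0.28 or above in every WT library, while the acute phase list of LKO replicate 3 (0.06) lies among the WT libraries.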

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

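Voom, library totals, quantile normalization, leaving out both replicate 1 libraries, array quality weights, protein-coding genes alone, GC correction and lists without multigene families were chosen after seeing the data. The planned fits with a count model, with its other size factors and with count-based filters were not run, since the files held FPKM. The main result was 1 gene higher and 4 lower in libraries labelled LKO, all at least 2-fold. The 5 called genes and 13 called lists kept their direction in every setting that tested them. For array quality weights this covers the genes and the list medians only. Camera was run without the weights, so its list calls there repeat the main ones. Both counts (1 and 4) stayed with a pseudocount of 0.1 and a mean of at least 1 FPKM; voom and library totals gave 1 and 5, GC correction 1 and 6.

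Without a filter 0 genes were higher and 1 lower, with 22574 genes tested. Quantile normalization gave 0 higher and 3 lower, leaving out both replicate 1 libraries 1 and 1 (fewer samples), and protein-coding genes alone 1 and 7. The at least 2-fold counts were the same in these settings. Array quality weights gave 621 higher and 574 lower, 357 and 323 of them at least 2-fold; they gave WT replicate 3 a weight of 5.44 and LKO replicate 1 a weight of 0.299, and with weights another split of the libraries called 199 genes. Beyond the counts named with their construction, the cause was not tested. Leaving out 1 library gave 0 to 13 genes higher and 0 to 4 lower, at least 2-fold 0 to 13 and 0 to 4, with the 0 and 0 without WT replicate 3 and the 13 without LKO replicate 3. Hsd3b5 lost its call without WT replicate 3 (adjusted p = 0.0600), Cdhr5 without WT replicate 1 or 3, Susd4 without WT replicate 1 or 3 or LKO replicate 2, Actg1 without any library but LKO replicate 3, and Gm31583 without any library. Arid2 ranged from -0.19 to 0.12 with 1 library left out. Hbb-bt turned from -0.66 to 0.047 with array quality weights. Over all lists tested, 0 were called with an estimated correlation, 0 with fry and 11 to 19 in the other settings. These were not always the same lists. Without both replicate 1 libraries 16 were called, 4 of them not called with all 6 libraries. No called gene lay near Arid2 with windows of 2 or 20 Mb (Fisher's exact test, p = 1), a test that 5 calls leave without power.

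The replicate numbers did not clearly pair the samples, but a pairing of the libraries numbered 1 is not excluded. Deviations from the group means correlated at 0.49, 0.30 and -0.02 for numbers 1, 2 and 3, and not every sample correlated best with its own number (WT replicate 2 with LKO replicate 3, 0.45). With the number as a replicate block, 0 genes were higher and 0 lower, at least 2-fold or not (limma; 1478 genes at an unadjusted p under 0.05), and 13 lists were called.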

Other observations

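All tests of explanations in this part were chosen after the results were seen, and those on gene copies, the acute phase response and exchanged libraries were revised after a first run, the acute phase test more than once. Lists not described above gave no call: camera adjusted p was 0.0905 for pericentral and 0.192 for periportal zonation markers, 0.148 for genes of the mitochondrial genome, 0.235 for the circadian clock, 0.626 for cholesterol synthesis and 0.886 for xenobiotic metabolism. Without both replicate 1 libraries camera with the preset correlation called 4 further lists. The mitochondrial genome (adjusted p = 5.73e-06; 0.946 as adjusted p with an estimated correlation) and sinusoidal endothelial markers (adjusted p = 3.39e-04; 0.751 as adjusted p with an estimated correlation) lay lower in LKO. Gluconeogenesis (adjusted p = 0.0144; 0.946 as adjusted p with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0396; 0.947 as adjusted p with an estimated correlation) lay higher.

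The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The labelled split gave 1 gene higher and 4 lower, 5 of them at least 2-fold; the highest count in any other split was 0 for each, and 1 split, the labelled one, gave as large a count. For gene lists the labelled split gave 13 and the highest other split 18, and 6 splits gave as many. The split of WT replicates 1 and 3 with LKO replicate 1 against the rest had 2595 genes at an unadjusted p under 0.05, against 1076 for the labelled split, which points to a structure of the libraries other than genotype. The male-biased, female-biased, interferon, lipid droplet, JAK-STAT and B and plasma cell lists had their smallest camera p in the labelled split. Another split came close for the female-biased (camera p 8.33e-08 against 1.36e-07) and interferon lists (8.04e-05 against 2.00e-04). Preset camera also called the male-biased list in other splits, with an adjusted p down to 2.19e-06. Fatty acid oxidation, acute phase and immediate early genes had a smaller camera p in 2 of the 9 others. The integrated stress, heat shock, erythroid and neutrophil lists also had a smaller one in another split.

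With the preset correlation, male-biased transcripts lay lower and female-biased ones higher in libraries labelled LKO, and female animals among these are argued against by the Y-linked genes, whose mean over 4 genes was 5.21 FPKM in the lowest LKO library and 4.44 in the lowest WT library. With the acute phase level of each library as a covariate, both lists kept their calls by preset camera (male-biased median -1.48, adjusted p = 1.02e-10; female-biased median 3.07, adjusted p = 1.54e-12) but neither was called with an estimated correlation (adjusted p = 0.509 for both, against 0.687 and 0.699 without the covariate), while the acute phase list lost its call by construction (median 0.13, adjusted p = 0.836). An acute phase response still cannot be told apart, because these values rested on LKO replicate 3, whose acute phase level lay among those of WT: without it the medians were -0.61 (adjusted p = 0.0416) and 0.81 (adjusted p = 0.0619). Reads moved between gene copies cannot account for the 6 male-biased genes outside multigene families, which says nothing about the members inside families. These 6 genes ran from -3.33 (Susd4) to -0.08 (C8a), with a median of -1.14, and only Susd4 passed over all genes. For the Mup family (log2 ratio of summed FPKM -0.73, with overlapping libraries) moved reads cannot be told apart. Whether the 4 female-biased genes outside families rose at all stays open (median 0.56, mean difference 0.96, 95% interval -0.56 to 2.49). The summed Mup FPKM was 10898, 19502 and 34578 in WT replicates 1 to 3 and 10612 to 14563 in LKO. A difference in genotype remains a candidate explanation, as do animal differences the labels do not give.

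Both replicate 1 libraries had few genes with 1 to 5 reads. Depth is argued against, since after all libraries were thinned to 13947787 reads they had at most 2368 such genes and the other 4 at least 4043. Mitochondrial transcripts taking the reads are argued against in the same way, with at most 2453 against at least 4112 after these genes were removed and the rest thinned. No biological explanation was tested, as the design names none for a replicate number.

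Arid2 was not lower in the libraries labelled LKO. An exchange of 1 WT with 1 LKO library cannot be told apart: the lowest Arid2 difference over the 9 exchanges was -0.30, but the 6 libraries span only 0.65 on the log2(FPKM + 1) scale, so no exchange could have given a fall of 1 log2 unit. A deletion of part of the gene that leaves most exons counted cannot be told apart from an intact gene with a whole-gene value (-0.049), because the files give no values per exon.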
